A study of Homo sapiens with 8 samples.

How the data were processed

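Gene expression of H9 human embryonic stem cells was measured on 8 Affymetrix expression arrays, 2 for each of 4 groups, which were unsorted undifferentiated cells at day 0 and KDR and CD31 positive cells sorted at day 4, day 6 and day 8 of differentiation toward blood. Per the labels' protocols, total RNA was extracted with Trizol, labelled as biotinylated cRNA, and the lines were maintained on mouse fibroblast feeder layers. Groups and replicate numbers were taken from the sample titles. For 3 samples of day 6 and day 8 the source name gives day 4, while title, description and stage agree among themselves on the later day, which was used.

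The authors deposited 1 intensity value per probe set and array, on a linear scale. Per the submitters' processing notes the tool was MAS5, of a version not given in the sources used here. The deposited values reach down to between 8.61 and 8.84 on each array and have nearly equal medians, from 88.7 to 93.2, so the exact summary and scaling steps stay unsettled, and no detection calls were used here. No scaling was added to the deposited values. They were transformed as log2(intensity + 32), so that folds are on that scale and understate the change of dim genes.

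The platform annotation gave 1 gene symbol for 41091 of 54675 probe sets, several for 1801 and none for 11721, and 62 were controls. By gene ID 41037 were found in a reference gene table, which changed 0 symbols. No gene was named from a probe set with several symbols, which is why POU5F1, RUNX1 and the fetal and alpha globins of the lists were not analysed here, and 78 of 850 list memberships had no probe set with 1 gene symbol. Per gene, the probe set with the highest mean over the 8 arrays was used, those ending in _x_at only where no other existed. Genes above the array median on at least 2 of 8 arrays were tested, 13647 of 19775. No genome build was named, so no coordinates are given.

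The test was limma 3.58.1 in R 4.3.3, with 1 fit over all 8 arrays, a term per group, eBayes with trend and Benjamini-Hochberg adjustment over all genes tested, called at 0.05, two-sided. The fit had 4 residual and 2.84 prior degrees of freedom. The comparisons were day 4 with day 0, day 6 with day 4, day 8 with day 6, day 8 with day 4, and day 6 and day 8 with day 0. Gene lists numbered 32, and all but the gate genes were tested as sets with camera at a preset correlation of 0.01, adjusted over 31 lists per comparison. The same lists were tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. A gene called on the list alone was adjusted over the tested members of its list. Lists share members, so their counts and tests are not independent of each other. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

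Before the data were examined, the groups, tests, lists, alternatives and the rule for named genes were set. The rule named, among genes past the threshold whose replicates do not overlap, the 8 largest rises and 8 largest falls from day 0 to day 4 and from day 4 to day 8, and 5 of each for the steps between. It also named up to 4 members past the threshold per list, the 2 members with the smallest p in a shifted list with fewer than 2 past it, and KDR, PECAM1, NANOG, TBXT, CDH5 and CD34 in every comparison, with POU5F1 and RUNX1, which were not analysed here.

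On simulated data made with the mean of each gene over the arrays, its residual spread and the relative spread of each group, 200 genes were changed per comparison among the 13647 tested. For day 4 against day 0, changes of 1, 2 and 3 on the log2 scale were recovered in 38.8%, 74.6% and 90.9% of genes with 4 false calls. For day 8 against day 4 the shares were 38.8%, 77.6% and 92.4% with 14 false calls.

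Alternatives were an offset of 1 or 128, no filter or a filter at the 75th percentile, quantile normalization, median centring, the mean of all probe sets of a gene, every probe set on its own, eBayes without trend, only the arrays of the groups compared, a replicate block, a minimum log2 change of 1, and each array left out in turn. Where an array is left out, the lone array of its group is assumed to vary like the other groups. Fits on the 6 sorted arrays, with and without a replicate block, and without replicate 1 of day 4 and of day 6 were added after the data were seen.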

Results

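H9, an established line of human embryonic stem cells, was followed from the undifferentiated state (day 0) through differentiation toward blood in a serum-free medium with BMP4. Cells bearing KDR, the main receptor of vascular endothelial growth factor, together with CD31, the endothelial adhesion molecule encoded by PECAM1, were sorted at day 4, day 6 and day 8. The day 0 cells were not sorted. RNA of each of the 4 groups was measured on 2 expression arrays, 8 in all, which the labels call biological replicates without saying whether they shared a culture or a day of work. The p-values therefore measure only the spread between these arrays, and their number limits the precision of each value. The median intensity lay between 88.7 and 93.2 units per array. Levels below are means of log2(intensity + 32), written as log2 intensity, with the SD of 2 arrays. The SE of a change comes from the spread within all 4 groups of the fit, not within the 2 compared alone.

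The day 0 arrays stood apart from the 6 sorted arrays on the first principal component, which held 70.3% of the variance over 13647 genes tested. On the second component, with 16.6%, replicate 1 of day 4 and replicate 1 of day 6 stood apart from the other 4 sorted arrays. Across genes, which are not independent replicates, Pearson's r between the 2 arrays of a group was 0.997 at day 0, 0.953 at day 4, 0.937 at day 6 and 0.980 at day 8. Replicate 1 of day 4 correlated more closely with replicate 1 of day 6 (r = 0.976) than with its own partner. Only 1 gene lay over 2-fold apart between the day 0 arrays, against 909 genes at day 4, 1262 at day 6 and 215 at day 8. The signal ratio of 3' to 5' probe sets for ACTB, a control for RNA integrity, was 19.0 and 31.0 on these 2 arrays and between 9.18 and 16.0 on the other sorted arrays. The ratio for GAPDH, the second such control, was 2.22 and 3.73 on them and between 2.15 and 3.41 on the other sorted arrays. By group, in replicate order, it was 1.71 and 1.91 at day 0, 2.22 and 2.15 at day 4, 3.73 and 3.41 at day 6, and 2.41 and 3.08 at day 8. The groups did not overlap in this ratio, so RNA integrity by this control was not separated from day in any comparison. The ACTB ratio was 8.92 and 10.4 at day 0 and 9.91 and 15.1 at day 8. It overlapped between groups except for day 6 with day 0 and with day 8.

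**Figure D1:**
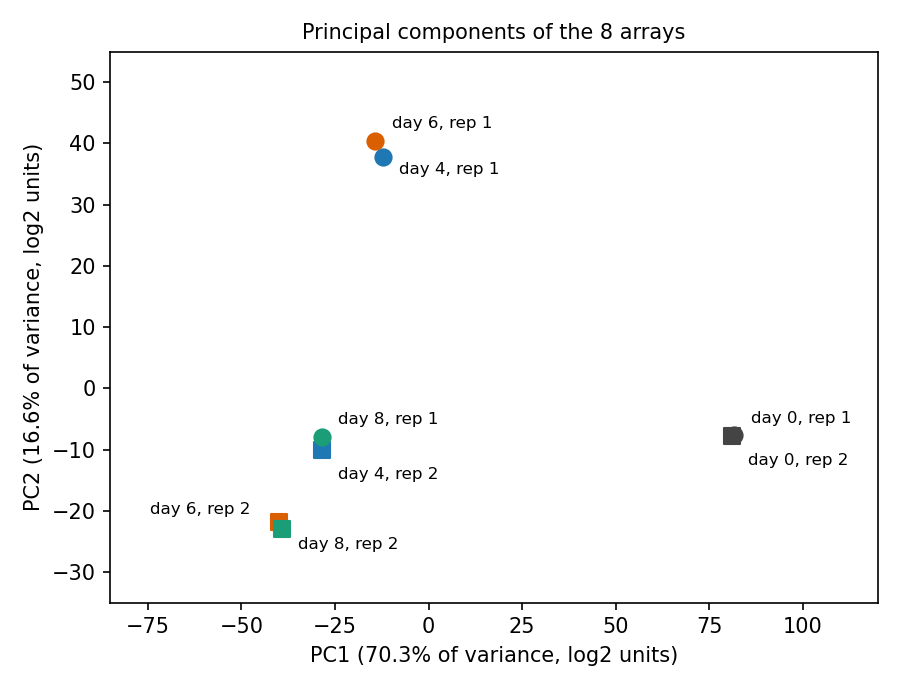
Position of each of the 8 arrays on the first 2 principal components of log2(intensity + 32), in log2 units, with circles for replicate 1 and squares for replicate 2. The day 0 arrays lie at the right, and replicate 1 of day 4 and of day 6 lie together at the top, at 37.8 and 40.4 on the second component.

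The comparison of day 4 with day 0 asked how the sorted KDR and CD31 positive cells differed from the undifferentiated culture. Among 54 endothelial genes 40 rose, and among 27 pluripotency genes 20 fell, by up to 127-fold and 93.0-fold on the scale used. Neither list shifted as a set by camera with an estimated correlation (adjusted p 0.149 and 0.106), which called 0 of 31 lists here. Both shifted by camera with the preset correlation and by fry (adjusted p 0.000301 and 5.46e-05 by fry). CDH5, the cadherin of endothelial junctions, went from a log2 intensity of 5.71 ± 0.03 (SD, n = 2) to 12.70 ± 0.63 (SD, n = 2), a rise of 6.99 ± 0.40 (SE). SOX2, a core transcription factor of pluripotency, fell by 6.54 ± 0.93 (SE) on the log2 scale, from 12.91 ± 0.01 to 6.37 ± 0.76. Of 13647 genes, 1163 rose and 1353 fell at an adjusted p under 0.05 in limma, and 790 and 903 of these differed at least 2-fold. The gate genes themselves rose 24.0-fold (KDR) and 85.6-fold (PECAM1), which the sort selects for and which is therefore no finding. Day and sorting changed together here and cannot be told apart.

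The other genes among the 8 largest rises were CD93 (102-fold), RASGRP3 (93.7-fold), ERG (86.3-fold), MMRN2 (84.8-fold), SOST (78.4-fold) and SAMSN1 (71.5-fold). CD93 and MMRN2 are endothelial surface and matrix proteins, and ERG is an ETS-family transcription factor of endothelium and blood stem cells. Apart from SOX2, the largest falls were of L1TD1 (68.3-fold), OTX2 (49.5-fold), ZIC2 (47.2-fold), CFAP95 (47.0-fold), CYP26A1 (44.6-fold) and NANOG (44.6-fold). NANOG is a core pluripotency factor, OTX2 and ZIC2 are homeobox and zinc-finger factors of early ectoderm, and CYP26A1 degrades retinoic acid. A probe set annotated to MIR302B also stood among the 8 largest falls, and its value is not given because it was not matched to the mature microRNA. All 8 genes of the largest rises lay below the array median on both day 0 arrays, as did SOX2 and NANOG on both day 4 arrays. Their folds therefore depend on the offset of 32. The same holds for genes named below that lay under the array median at day 0 or day 4, such as EMCN and TAL1. With a smaller and a larger offset the log2 change was 8.28 and 5.51 for CDH5 and -7.32 and -5.42 for SOX2, and 8 and 6 of these 8 rises and 6 and 7 of the 8 falls stayed among the 8 largest. The adjusted p of the genes named here was between 2.59e-06 and 0.00652. The fall of ZIC2 missed the threshold when either day 0 array was left out, with an adjusted p of 0.0629 or 0.0576.

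Of 54 endothelial genes tested, 40 rose, 1 fell and 13 did not pass, or 45 rose and 1 fell when adjusted over the list alone, and the median change was 3.37 on the log2 scale. FLI1, an ETS-family factor, rose 64.4-fold and CD34, a marker of endothelium and blood progenitors, rose 14.5-fold from 7.51 ± 0.08 to 11.36 ± 0.10. CD34 lay just past the limit (adjusted p = 0.0504) when replicate 1 of day 0 was left out. The list as a set was higher at day 4 than other genes by camera with a preset correlation (adjusted p = 5.58e-26) and not with an estimated correlation (adjusted p = 0.149). Of 7 venous genes 6 rose, among them APLNR, the apelin receptor (45.7-fold), EMCN (43.9-fold), the angiopoietin receptor TEK (3.99 on the log2 scale) and NRP2 (7.52-fold). APLNR, EMCN and TEK are also on the endothelial list, and of the 4 venous genes that are not, 3 rose. Of 22 arterial and Notch genes 10 rose and none fell, among them the gap junction genes GJA4 (20.4-fold) and GJA5 (20.3-fold), SOX17 (15.9-fold) and the Notch target HEY1 (10.7-fold). Both lists shifted with the preset correlation, and with an estimated correlation the adjusted p was 0.106 for venous and 0.586 for arterial genes. GJA5 missed the threshold without either day 0 array (adjusted p 0.078 and 0.0828) and without replicate 2 of day 4 (adjusted p = 0.0517), and GJA4 without replicate 2 of day 0 (adjusted p = 0.0618).

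TAL1, a transcription factor required for blood formation, rose 51.7-fold from 6.17 ± 0.16 to 11.86 ± 0.48 (SD, n = 2), and MYCT1 rose 50.1-fold. Of 40 genes of haematopoietic stem and progenitor cells, 22 rose and 3 fell. However, 8 of the 40, with TAL1 and MYCT1 among them, are also on the endothelial list. Of the 32 that are not, 14 rose and 3 fell. Set tests gave an adjusted p of 4.18e-08 with the preset and 0.33 with an estimated correlation. In the myeloid list 4 of 14 genes rose, namely LAPTM5 (42.1-fold), the mannose receptor MRC1 (26.6-fold), CSF2RB (9.69-fold) and FCER1G (1.75-fold). In the megakaryocyte and platelet list 4 of 23 rose, namely FLI1, the thrombin receptors F2RL2 (21.9-fold) and F2R (2.17-fold), and VWF (7.74-fold), the clotting factor also made by endothelium. FLI1 and VWF are also on the endothelial list, and of the 21 that are not, 2 rose. Both of these lists shifted with the preset correlation (adjusted p = 0.667 with an estimated correlation for each) and neither did without replicate 2 of day 4. The erythroid list did not shift as a set by camera (adjusted p = 0.292) or fry (adjusted p = 0.173), though RHAG rose 12.3-fold, CA2 5.64-fold and KLF1 1.69-fold, and the transferrin receptor TFRC fell by 2.14 on the log2 scale. The CA2 call was lost without any 1 array of day 0 or day 4 (adjusted p 0.0611 to 0.146), and the KLF1 call without any 1 array of day 0, day 4 or day 8 (adjusted p 0.0551 to 0.241). In the lymphoid list, which fry called (adjusted p = 0.0272) and camera with the preset correlation did not (adjusted p = 0.0932), GATA3 rose 3.53-fold, CD79B 3.19-fold and EBF1 2.21-fold, and LCK fell by 2.52.

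Of 27 pluripotency genes 20 fell and 1, THY1, rose, with a median change of -2.09 on the log2 scale. USP44, a deubiquitinase of undifferentiated cells, fell 34.6-fold. With the estimated correlation the adjusted p of the list was 0.106, against 5.11e-15 with the preset correlation. In the list of DNA methylation and chromatin regulators 5 of 24 genes fell, among them the demethylase TET1 (5.44-fold), the helicase HELLS (4.34-fold), the methyltransferase DNMT3B (4.27-fold) and JARID2 (3.78-fold), the last pair also on the pluripotency list, with an adjusted p of 0.216 with an estimated correlation. Of 17 genes of neural and surface ectoderm 6 fell, among them OTX2, STMN2 (16.4-fold), TFAP2A (7.60-fold) and DCX (5.14-fold). That list had an adjusted p of 0.0015 with the preset and 0.586 with an estimated correlation. TBXT, the brachyury gene of the primitive streak, was at 7.95 ± 0.04 at day 0 and 7.94 ± 0.07 at day 4 (adjusted p = 0.987). Of 8 primitive streak genes 1, EOMES, fell by 1.86, and that list did not shift as a set by camera (adjusted p = 0.292) or fry (adjusted p = 0.0565).

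Genes of other cell types also moved, some higher in the sorted cells and some higher in the unsorted day 0 culture. Of 24 genes of cardiac and lateral mesoderm 6 rose and 1 fell, among the former MEF2C (27.2-fold), GATA6 (6.21-fold), WT1 (5.46-fold) and GATA4 (4.47-fold). Of 16 endoderm genes 4 rose and 1 fell. The 4 were SOX17, HHEX (10.8-fold), GATA6 and GATA4, each of which also stands in the endothelial or cardiac list. Plasma protein genes of the endoderm list, chosen for mention after their values were seen, differed between the 2 day 4 arrays. APOA2 had a log2 intensity of 9.18 and 13.21 on them and AFP 10.84 and 12.99, against day 0 means of 8.32 and 8.28. Of 26 genes of smooth muscle and fibroblasts 8 fell and 1 rose, among the former TAGLN (10.8-fold), COL1A1 (10.1-fold), LOX (9.56-fold) and MYL9 (5.38-fold). These 3 lists had an adjusted p of 0.0401, 0.00266 and 0.0324 with the preset correlation, and of 0.667, 0.586 and 0.667 with an estimated correlation. The endoderm and fibroblast calls ended without replicate 2 of day 4 (adjusted p 0.127 and 0.0764), where the endoderm median went from 2.38 to 0.91, and the cardiac call ended without replicate 1 of day 4 (adjusted p = 0.192), where its median went from 0.36 to 0.01, of day 0 (adjusted p = 0.0554) or of day 6 (adjusted p = 0.0628).

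Of 9 HOXA and HOXB genes 6 rose, among them HOXB6 (10.5-fold), HOXB7 (8.86-fold), HOXB3 (3.79-fold) and HOXB5 (2.45-fold), with an adjusted p of 0.000562 with the preset and 0.586 with an estimated correlation. In the list of DNA replication and S phase, which had an adjusted p of 0.0455 with the preset and 0.907 with an estimated correlation, MCM4 alone fell, by 1.34, of 38 genes. GINS1 of that list differed by -1.57 (adjusted p = 0.0879) and passed without either day 6 array. The call of this list ended without replicate 2 of day 4, with a median change of 0.03 and an adjusted p of 0.773.

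No other list shifted as a set by camera with the preset correlation, while fry also called the interferon response (adjusted p = 0.0272) and VEGF response lists (adjusted p = 0.0451). Members past the threshold went both ways among BMP and SMAD targets (4 rose, 3 fell), VEGF response genes (4 and 3), p53 response and growth arrest (4 and 4), hypoxia response (3 and 3), immediate early and dissociation stress (3 and 5), interferon response (3 and 5), WNT targets and inhibitors (1 and 6), trophoblast and amnion (1 and 1) and MHC class II and antigen presentation (1 and 1). Among these, the BMP antagonist GREM1 fell 23.3-fold, ID4 fell 7.43-fold and BMPER rose by 3.17 on the log2 scale. The WNT modulator SFRP2 fell 30.6-fold, the receptor FZD7 6.89-fold and AXIN2 3.29-fold, while LEF1 rose 3.19-fold. HLX rose 13.1-fold and KLF2, a flow-responsive factor of endothelium, 8.61-fold, and F3, or tissue factor, fell 4.45-fold. PMAIP1, a pro-apoptotic gene, fell 25.9-fold while the kinase gene PLK2 rose 7.52-fold, and GADD45B and the cell cycle inhibitor CDKN2B fell 3.90-fold and 2.59-fold. The immunoproteasome genes PSMB8 and PSMB9 fell 8.56-fold and 5.57-fold, IFITM1 fell 5.84-fold, and IFIT3, an interferon-induced gene, rose 4.61-fold. HLA-DRB1 rose 1.94-fold and HLA-DMA fell 1.75-fold. TFAP2C, a trophoblast and germ cell factor, fell 7.68-fold. The immediate early genes ATF3, IER3, CCN1 and FOS fell 4.76-fold, 3.71-fold, 3.62-fold and 3.02-fold. The FOS call was lost without any 1 array of day 0 or day 4 (adjusted p 0.0759 to 0.196), the CCN1 call without 5 of the 8 arrays in turn (adjusted p 0.0617 to 0.228), the IER3 call without 3 (adjusted p 0.0914 to 0.14) and the ATF3 call without replicate 1 of day 0 (adjusted p = 0.0525). STC2 and ADM, which hypoxia induces, fell 5.16-fold and 3.79-fold, and the oxygen sensor EGLN1 rose 2.70-fold. Of 16 basement membrane genes 3 rose, COL15A1 (3.46 on the log2 scale), NID2 (5.28-fold) and NID1 (4.81-fold). SLC2A3, a glucose transporter, rose 1.93-fold as the only changed gene of 19 in glycolysis, and none of 38 mitosis, 42 oxidative phosphorylation and 18 cholesterol synthesis genes passed.

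The count of this comparison fell most when a day 0 array was left out. Without replicate 1 of day 0 the count of changed genes was 646, of which 645 were among the 2516, and without replicate 2 it was 650. Without replicate 1 of day 4 and of day 6 together, a choice made after the data were seen, it was 4755, which held 2451 of the 2516. Of 99 genes named by rule and called here, 42 lost their call without at least 1 of the day 0 arrays. For 20 of these the call was also lost without an array of day 4, namely CA2, KLF1, FCER1G, EBF1, DCX, TAGLN, ID4, SFRP2, FZD7, AXIN2, LEF1, HOXB5, MCM4, GADD45B, IER3, CCN1, FOS, ADM, HLA-DRB1 and GJA5. The others were ZIC2, CD34, GJA4, WT1, GATA4, F2R, CD79B, COL1A1, LOX, MYL9, COL15A1, NID2, NID1, GREM1, HOXB3, ATF3, STC2, IFITM1, IFIT3, HLA-DMA, HELLS and JARID2.

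**Figure D2:**
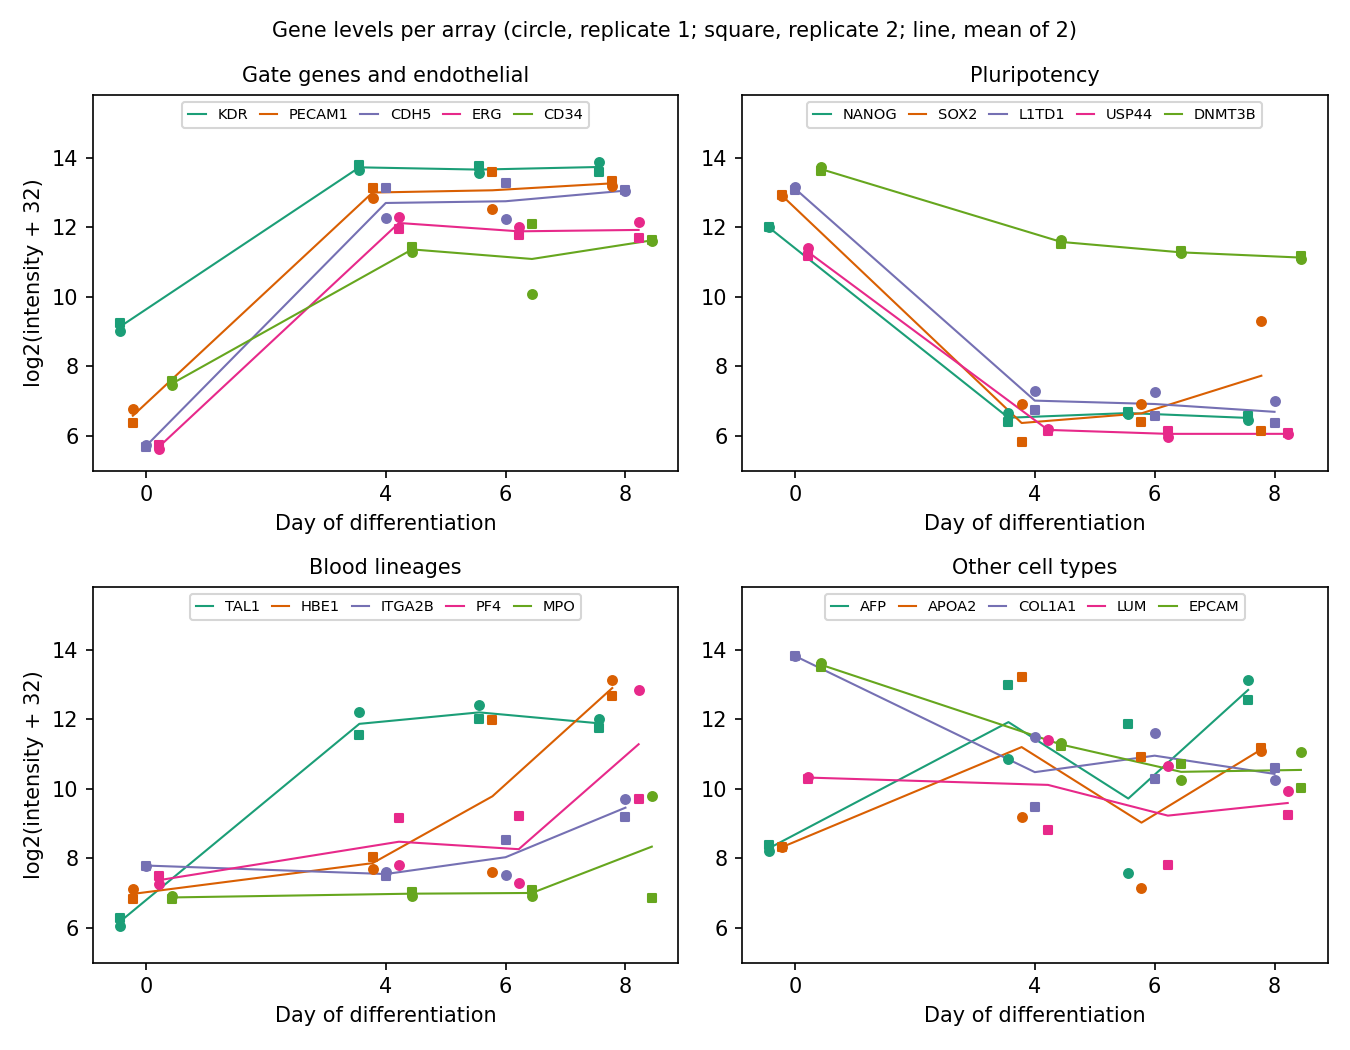
Levels of 20 genes per array as log2(intensity + 32) against the day of differentiation, in 4 panels, with circles for replicate 1, squares for replicate 2 and lines through the mean of 2. CDH5 went from 5.71 at day 0 to 12.70 at day 4, NANOG from 12.00 to 6.52, and HBE1 was at 12.90 at day 8, with the 2 day 6 arrays far apart.

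Set against day 0, the later sorted groups gave 3187 changed genes at day 6 (1328 higher and 1859 lower) and 3345 at day 8 (1422 higher and 1923 lower). These comparisons use the same 2 day 0 arrays as the comparison at day 4, so no overlap between them was counted. The largest loss came from leaving out a day 0 array, with 849 genes at day 6 without replicate 2 and 869 at day 8 without replicate 1.

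The step from day 4 to day 6 asked what changed within the sorted gate, and no gene passed the threshold in limma. At an unadjusted p under 0.05 there were 722 genes, against 682 expected by chance. KDR differed by -0.06 ± 0.17 (SE), PECAM1 by 0.06 ± 0.35, CDH5 by 0.05 ± 0.40, CD34 by -0.27 ± 0.57, NANOG by 0.13 ± 0.14 and TBXT by -0.13 ± 0.15, each by less than its error. HBE1, the embryonic beta-like globin, was at 7.59 and 11.97 on the 2 day 6 arrays, against 7.68 and 8.03 at day 4. With replicate 1 of day 6 left out, HBE1 was higher at day 6 by 4.11 on the log2 scale. ALAS2, the enzyme that starts haem synthesis in red cells, was higher by 1.82. With replicate 2 left out, LHX1 was higher by 2.58. Each change rests on the day 6 array kept, which for LHX1 is replicate 1, the array that stood apart. These genes were named after their values were seen.

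As sets, 6 of 31 lists shifted from day 4 to day 6 with the preset correlation, none with an estimated correlation (adjusted p from 0.59 to 0.744 for the 6) and none by fry (smallest adjusted p = 0.308). No member of these lists passed the threshold, and outside them the Notch target HES1 fell by 0.98 when adjusted over the arterial list alone. Of 42 oxidative phosphorylation genes 41 were lower on average, with a median change of -0.29, and NDUFA1 and NDUFA2 of respiratory complex I differed by -0.72 ± 0.18 and -0.82 ± 0.22 (SE). Of 24 hypoxia response genes 20 were higher, with a median of 0.37, and PFKFB3 and EGLN3 differed by 0.64 ± 0.17 and 1.07 ± 0.46. Lower as sets were also immediate early genes (median -0.35), with FOS at -1.30 ± 0.39 and DUSP1 at -0.91 ± 0.25, and interferon response genes (median -0.23), with IFI35 at -0.44 ± 0.13 and IFIT1 at -0.79 ± 0.31. BMP and SMAD targets (median -0.16), with SMAD9 going from 8.32 to 7.31 and ID3 at -0.78 ± 0.26, and endoderm genes (median -0.78), with RBP4 at -1.87 ± 0.89 and FGB at -1.64 ± 0.88, were lower too. Each of these 6 calls was lost without 1 array of day 4 or day 6. The oxidative phosphorylation and immediate early calls were lost without replicate 2 of day 6 (adjusted p 0.253 and 0.462), where the medians were 0.02 and -0.07, and the hypoxia call without replicate 2 of either day (medians 0.16 and 0.20, adjusted p 0.071 and 0.684). The BMP call was lost without replicate 2 of either day, the interferon call without replicate 2 of day 4 or replicate 1 of day 6, and the test of the endoderm list changed direction without replicate 2 of day 4 and lost its call without replicate 1 of day 6 or either day 8 array.

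No gene passed the threshold in the step from day 6 to day 8 either, where 338 genes had an unadjusted p under 0.05, against 682 expected by chance. The differences were 0.07 ± 0.17 (SE) for KDR, 0.20 ± 0.35 for PECAM1, 0.31 ± 0.40 for CDH5, 0.53 ± 0.57 for CD34, -0.14 ± 0.14 for NANOG and 0.13 ± 0.15 for TBXT. Without replicate 2 of day 6 the step rests on replicate 1 of that day, which stood apart from most sorted arrays. Against it the globins HBE1 (5.30) and HBD (2.15), ALAS2 (1.91), CAVIN2 (2.09), EEF2 (1.56) and CYSLTR1 (1.34) were higher at day 8 on the log2 scale. LHX1 (-2.94) and FAM222A (-1.89) were lower. Without replicate 2 of day 8, LYZ (3.52) and the granulocyte enzyme gene MPO (2.80) were higher, which rests on the other day 8 array. These genes were named after their values were seen.

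With the preset correlation 13 of 31 lists shifted from day 6 to day 8, 10 up and 3 down, and none did with an estimated correlation (adjusted p = 0.699 for each of the 13) or by fry (smallest adjusted p = 0.742). Blood lists were among those higher at day 8. In the megakaryocyte list 19 of 23 genes were higher (median 0.37), with ITGA2B, the platelet integrin CD41, at 1.42 ± 0.34 (SE) and RAB27B at 2.23 ± 0.59. In the myeloid list 14 of 14 were higher (median 0.25), with FCER1G at 0.43 ± 0.18 and LYZ, or lysozyme, at 1.90 ± 0.89. In the erythroid list 16 of 23 were higher (median 0.21), with HBD at 1.44 ± 0.40 and SLC4A1 at 0.38 ± 0.13. In the haematopoietic progenitor list 30 of 40 were higher (median 0.20), with ITGA2B and ANGPT1 (1.06 ± 0.30). With 1 array left out the megakaryocyte median ran from 0.11 to 0.63 and the call held, but it ended without replicate 1 of day 4 and of day 6 together (median 0.11, adjusted p = 0.0781), a choice made after the data were seen. The erythroid call was lost without replicate 1 of day 8 and the myeloid call without replicate 1 of day 6, and the haematopoietic progenitor median turned to -0.06 without replicate 1 of day 6. The myeloid median ran from 0.03 to 0.47 with 1 array left out.

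Endothelial, arterial and venous lists were higher at day 8 too, and the direction of the first pair rested on replicate 1 of day 6. The endothelial median of 0.23 (LYVE1 1.24 ± 0.20, APLNR 0.51 ± 0.19) became -0.10 without that array, and the arterial and Notch median of 0.31 (HEY2 -0.91 ± 0.34, HES1 0.32 ± 0.19) became -0.27 with an adjusted p of 0.0117. LYVE1, a lymphatic and embryonic endothelial receptor, was higher at day 8 when adjusted over the list alone (adjusted p = 0.0245), and HLA-DMA, of a list that did not shift here, was lower by the same measure (adjusted p = 0.0444). Basement membrane genes (median 0.47; COL15A1 1.26 ± 0.52, SPARC 0.31 ± 0.21) became -0.12. Mitosis genes, lower at day 8 in 37 of 38 (median -0.52; TTK -0.95 ± 0.73, CENPA -0.34 ± 0.27), became higher without it, at 0.29 with an adjusted p of 0.00473. Cardiac mesoderm genes (median -0.21; GATA4 -1.02 ± 0.47, FOXF1 0.94 ± 0.36) became 0.04. HOXA and HOXB genes (median 0.66; HOXB7 0.87 ± 0.38, HOXB3 0.74 ± 0.32) and endoderm genes (median 1.22; SERPINA1 1.49 ± 0.51, TF 0.31 ± 0.12) kept their direction but not their call without it. With 1 array left out, the medians of these 2 lists went as low as 0.26 and 0.25. Venous genes (median 0.38; NRP2 0.55 ± 0.18, APLNR) lost their call without replicate 2 of day 6 or either day 8 array. Hypoxia response genes were lower at day 8 (median -0.36; VEGFA -0.94 ± 0.22, MXI1 -0.92 ± 0.29), and lost the call without replicate 2 of day 6 (adjusted p = 0.944) or replicate 1 of day 8 (adjusted p = 0.0674). Without replicate 1 of day 8 the endothelial, arterial, cardiac and endoderm calls were lost as well, and the cardiac call also without replicate 2 of day 8 or either day 4 array.

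Over the whole span from day 4 to day 8, HBE1 had the highest fold among the erythroid genes named by rule, from 7.86 ± 0.25 to 12.90 ± 0.33 (SD, n = 2), 32.9-fold, although neither it nor any other gene passed the threshold over all genes. Its adjusted p was 0.724, and 0.103 in a fit of the day 4 and day 8 arrays alone, in which no gene passed either. The 2 day 6 arrays lay at 7.59 and 11.97 for HBE1. With either day 6 array left out, HBE1, ALAS2 and HBD were the 3 genes that passed, with changes of 5.04, 1.90 and 1.88 and adjusted p between 0.0075 and 0.0163. Without replicate 2 of day 8, LYZ and MPO were the 2 that passed (adjusted p = 0.0321 for each). At an unadjusted p under 0.05 there were 887 genes, against 682 by chance. Adjusted over the list alone, 6 erythroid genes rose, HBE1, HBD (3.67-fold), the embryonic alpha-like globin HBZ (5.76-fold), ALAS2 (3.73-fold), TFRC (2.24-fold) and the erythroid factor KLF1 (1.59-fold), of which the last 4 were named after their values were seen. On the same basis ITGA2B (3.75-fold) and RAB27B (6.31-fold) of the megakaryocyte list and LYVE1 (2.54-fold) of the endothelial list rose, and HLA-DMA of the MHC class II list fell by 0.66.

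From day 4 to day 8 the gate genes, CDH5 and CD34 differed by less than their errors, 0.01 ± 0.17 (SE) for KDR, 0.26 ± 0.35 for PECAM1, 0.36 ± 0.40 for CDH5 and 0.26 ± 0.57 for CD34. These errors include the spread of the day 6 arrays, which for CD34 lay at 10.08 and 12.09. CD34 was at 11.29 and 11.43 at day 4 and at 11.60 and 11.64 at day 8. The arrays of day 4 and day 8 did not overlap for CD34 and PECAM1 and did for KDR and CDH5. NANOG differed by -0.01 ± 0.14 and TBXT by -0.00 ± 0.15. With the preset correlation 13 of 31 lists shifted, 7 up and 6 down, and none did with an estimated correlation (smallest adjusted p = 0.457) or by fry (smallest adjusted p = 0.0869). Erythroid (15 of 23 higher, median 0.21), megakaryocyte (19 of 23, median 0.23), haematopoietic progenitor (30 of 40, median 0.19) and myeloid genes (14 of 14, median 0.16) were higher at day 8. In the latter lists ADGRG1 differed by 0.70 ± 0.20, MRC1 by 1.14 ± 0.43 and LYZ by 2.14 ± 0.89, with LYZ at 11.22 on 1 day 8 array and 7.99 on the other. These 4 calls held in each left-out array, with the erythroid median between 0.06 and 0.21 and the megakaryocyte median between 0.18 and 0.40. The endothelial (median 0.20, ROBO4 1.19 ± 0.48), basement membrane (median 0.52, LAMA4 2.27 ± 0.98, AGRN 0.75 ± 0.32) and arterial lists (median 0.28, HES1 -0.66 ± 0.19, HEY2 -0.82 ± 0.34) were higher too. They lost their calls without replicate 1 of day 4, where the test of the arterial list changed direction, and the arterial call was also lost without replicate 1 of day 8. With 1 array left out, the endothelial median went as low as 0.06 and the basement membrane median as low as 0.16.

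Oxidative phosphorylation genes were lower at day 8 than at day 4 in 40 of 42 (median -0.40), with NDUFA2 at -0.89 ± 0.22 (SE) and NDUFA1 at -0.65 ± 0.18, a call that held in each left-out array. The GAPDH ratio was higher on both day 8 arrays (2.41 and 3.08) than on both day 4 arrays (2.22 and 2.15), and no list call between sorted days was adjusted for it. Mitosis genes were lower in 37 of 38 (median -0.75; CENPA -0.81 ± 0.27, MYBL2 -0.63 ± 0.31) and S phase genes in 34 of 38 (median -0.37; PCNA -0.61 ± 0.30, CDC6 -0.76 ± 0.46). Without replicate 1 of day 4 the mitosis call ended (median -0.17, adjusted p = 0.348) and the test of the S phase list changed direction, and without replicate 2 of day 8 the S phase call was lost (median -0.20, adjusted p = 0.177). Cardiac and lateral mesoderm genes were lower in 21 of 24 (median -0.43), with GATA4 at -1.89 ± 0.47 and WT1 at -1.45 ± 0.37, a call lost without replicate 1 of day 4 (adjusted p = 0.158). BMP and SMAD targets (median -0.46; SMAD9 -1.03 ± 0.25, ID3 -0.72 ± 0.26) and MHC class II genes (median -0.40; HLA-DMA -0.66 ± 0.13, HLA-DRB1 -0.52 ± 0.24) were also lower, and both calls were lost without replicate 2 of day 4 (adjusted p 0.223 and 0.17) and the MHC class II call without replicate 1 of day 8 (adjusted p = 0.0532). With 1 array left out, the median ran from -0.49 to -0.38 for BMP and SMAD targets and from -0.42 to -0.37 for MHC class II genes. Estimated-correlation values for the 13 lists that shifted from day 4 to day 8 ran from an adjusted p of 0.457 to 0.894.

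**Figure D3:**
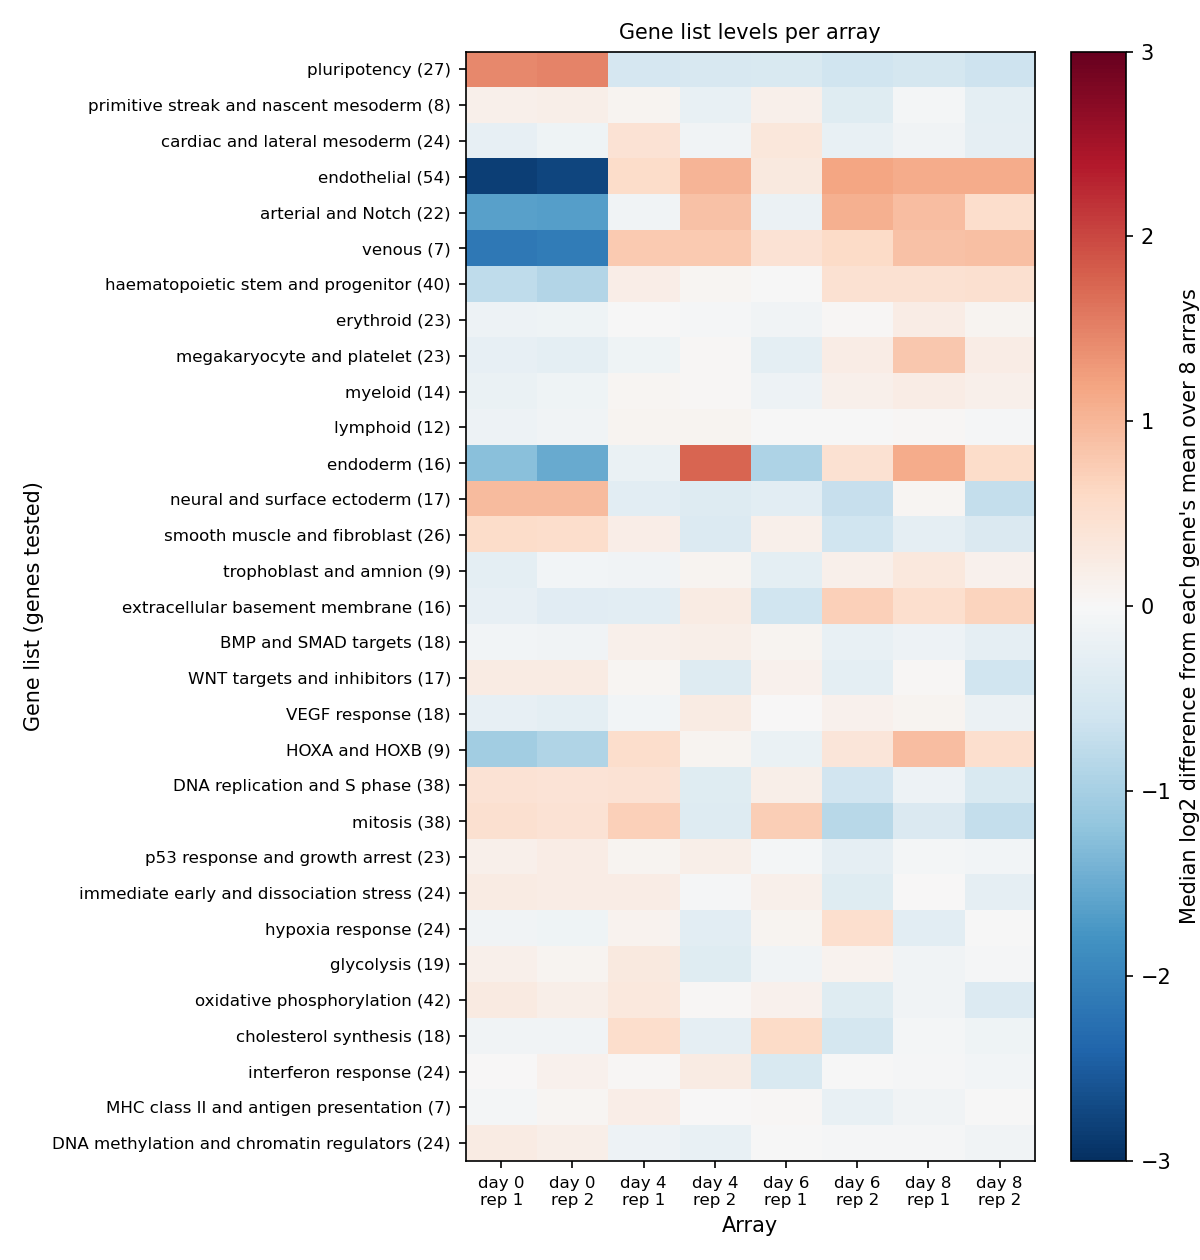
Median log2 difference of each gene list from its genes' means over the 8 arrays, per array (columns) and list (rows, with the genes tested in brackets). The 54 endothelial genes are low and the 27 pluripotency genes high on the day 0 arrays, and the endoderm row differs between the 2 arrays of day 4 and of day 6.

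No gene changed both in the step from day 0 to day 4 and in the step from day 6 to day 8, as none passed in the latter. Without replicate 2 of day 6, where that day rests on replicate 1, which stood apart, CAVIN2, CYSLTR1 and HBE1 rose in both steps. On the same basis EEF2 (-0.45, then 1.56) and FAM222A (0.70, then -1.89 on the log2 scale) went in opposite directions. Without replicate 2 of day 8, LYZ rose in both, which rests on the other day 8 array. All were named after their values were seen.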

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

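Probe sets without a single gene name take no part in the comparisons above. Of 5467 such probe sets that passed the same filter, 165 were higher and 273 lower at day 4 than in the unsorted day 0 arrays by limma at an adjusted p under 0.05. They stand out only as signal in data that the report does not use. The changed share was 8.01%, against 18.4% of the genes tested, and no explanation was tested.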

How the results depend on the processing

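The 8 arrays allow 4 residual degrees of freedom, no detection calls were used, and genes near the array floor carry little information. The settings changed no direction of a named gene called from day 0 to day 4, and 57 of 99 such genes stayed past the threshold in each setting run. Of the rest, 39 lost their call without replicate 1 of day 0 and 39 without replicate 2. Offsets, scalings and filters kept the count of day 4 against day 0 between 1983 and 2647. The causes of the changes below were not tested, except that every probe set counts several per gene and a minimum change removes genes.

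With every probe set tested, the counts were 3943 (day 4 against day 0), 5011 (day 6 against day 0) and 5217 (day 8 against day 0). A minimum log2 change of 1 gave 2006 and 2127 for the latter 2, and using only the arrays of the groups gave 6784 at day 8. Leaving out replicate 1 of day 4 and of day 6, chosen after the data were seen, gave 4755, 6079 and 6768 against day 0, 21 genes for day 8 against day 4, and 19 shifted lists for day 6 against day 4. With each array left out in turn the counts ran from 646 to 3155 (day 4 against day 0), 849 to 3594 (day 6 against day 0), 869 to 4372 (day 8 against day 0), 0 to 2 (day 6 against day 4), 0 to 8 (day 8 against day 6), 0 to 3 (day 8 against day 4) and 0 to 5 (both steps). Shifted lists ran from 9 to 16, 5 to 18 and 7 to 16 for the steps in time order. With an estimated correlation 0 lists were called in any of the 4 comparisons, and by fry 0 in the 3 among sorted days. For day 4 against day 0 fry called 14, among them lymphoid, interferon response and VEGF response genes, which camera did not call, but not cardiac mesoderm and fibroblast (adjusted p = 0.0571 for each) or S phase genes (adjusted p = 0.516). The S phase call also ended with the larger offset (adjusted p = 0.0534) and the cardiac call with the mean of probe sets (adjusted p = 0.0639).

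Medians of lists that reversed from day 6 to day 8, without replicate 1 of day 6 and then without replicate 1 of day 4 and day 6, were 0.0360 and 0.0360 for cardiac mesoderm, -0.10 and -0.10 for endothelial, -0.27 and -0.27 for arterial (adjusted p 0.0117 and 3.19e-05), -0.0573 and -0.0590 for haematopoietic progenitor, -0.12 and -0.12 for basement membrane and 0.29 and 0.29 for mitosis genes. Over all arrays left out they ran from -0.58 to 0.0360, -0.10 to 0.52, -0.27 to 0.88, -0.0573 to 0.34, -0.12 to 1.11 and -1.29 to 0.29 in that order. With the filter at the 75th percentile the test of cardiac genes reversed, with a median of -0.0547. Other settings ended further list calls, with these adjusted p. From day 4 to day 6 they were no filter for endoderm (0.0774) and BMP (0.0722), the 75th percentile for endoderm (0.0684), BMP (0.123) and interferon (0.0537), and the mean of probe sets for BMP genes (0.0747). From day 6 to day 8 they were the mean of probe sets (0.148) and no trend (0.0555) for cardiac and the 75th percentile for erythroid genes (0.0557). From day 4 to day 8 they were the 75th percentile for cardiac (0.463) and S phase (0.0829), quantile normalization for S phase (0.0614), median centring for arterial (0.0776), and no filter for BMP (0.0596) and MHC class II genes (0.206). For day 8 against day 4 the arterial median ran from -0.0157 to 0.80 and the S phase median from -0.77 to 0.00266, with the -0.0157 and 0.00266 obtained without replicate 1 of day 4, and without replicate 1 of day 4 and day 6 they were -0.0254 and 0.00266. With the direction of the test kept, the oxidative phosphorylation median from day 4 to day 6 ran from -0.51 to 0.0248, the latter without replicate 2 of day 6. The S phase median from day 0 to day 4 ran from -0.84 to 0.0296, the latter without replicate 2 of day 4. The endoderm median from day 4 to day 6 ran from -1.57 to -0.13, the latter without replicate 2 of day 4, where the test turned upward.

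Replicate numbers occur in every group, so a replicate block was fitted. Differences between replicates correlated at 0.600 (day 4 with day 6), 0.407 (day 6 with day 8) and 0.188 (day 4 with day 8), and at -0.02, 0.02 and 0.02 between day 0 and the others. The replicate block gave 3039 changed genes for day 4 against day 0, 2496 of them among the 2516, and 3874 and 4250 for day 6 and day 8 against day 0. It gave 0 among sorted days, and changed no list call among those made.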

Other observations

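All genes in this part beyond those named by rule were chosen, and all tests below were written, after the values were seen. Replicate 1 of day 4 and of day 6 differed from their partners in similar genes. Of 909 genes over 2-fold apart at day 4 and 1262 at day 6, 430 were shared and 426 of these went in the same direction, against 84.1 shared if the lists were independent. Mitosis genes were at least 2-fold higher in replicate 1 at both days in 22 of 38 tested, for example TTK 2.83-fold and 4.37-fold and NDC80 3.54-fold and 5.64-fold at day 4 and day 6. Of 26 smooth muscle and fibroblast genes 8 were higher by this measure and none lower, with LUM at 6.06-fold and 7.09-fold, and IGFBP7, which is not on that list, was 12.0-fold and 10.4-fold higher in replicate 1. At least 2-fold lower in replicate 1 at both days were 9 of 22 arterial and Notch genes and 8 of 16 endoderm genes. So were 7 of 54 endothelial genes, with none higher, and 3 of 16 basement membrane genes. The endothelial median of replicate 1 minus replicate 2 was -0.36 at day 4 and -0.53 at day 6. The gate gene PECAM1 stood at 12.85 and 13.14 at day 4 and 12.53 and 13.59 at day 6. KDR stood at 13.65 and 13.79, then 13.55 and 13.76. Whether the sort differed between replicates was not tested. For the chemokine receptor CXCR4 replicate 1 minus replicate 2 was -1.98 and -2.93 on the log2 scale, and for IGFBP3 -1.22 and -3.28.

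The 8 plasma protein genes of the endoderm list, AFP, APOA2, APOB, TTR, FGA, FGB, SERPINA1 and RBP4, had a median difference from day 0 of 0.87 and 3.98 on the day 4 arrays, -0.70 and 1.85 on the day 6 arrays and 2.57 and 2.34 on the day 8 arrays, in replicate order. Some lists and single genes also differed between the day 8 arrays. The neural and surface ectoderm list differed most, with a median of replicate 1 minus replicate 2 of 0.67 over 17 genes. DCX and STMN2 of that list stood at 7.76 and 8.92 on replicate 1 and at 5.98 and 7.33 on replicate 2. The median of the pluripotency list was 0.16. Replicate 1 of day 8 was higher on the log2 scale by 3.12 for PF4, a platelet chemokine, by 2.94 for MPO, the myeloperoxidase of granulocytes, by 3.23 for LYZ and by 3.18 for SOX2. The blood lists as a whole differed by less, with a median of replicate 1 minus replicate 2 of 0.05 for myeloid, 0.06 for haematopoietic progenitor, 0.21 for erythroid and 0.35 for megakaryocyte genes, and MYB (-0.56) and GATA1 (-0.26) were lower in replicate 1. MPO stood at 9.80 on that array and between 6.84 and 7.08 on the other 7. Without replicate 1 of day 4 and of day 6, the change from day 4 to day 8 rests on replicate 2 of day 4. Among the genes that passed on that basis, HBE1, ALAS2, HBD and TFRC were higher and APOA2, APOB, KRT19 and GATA5 lower at day 8. APOA2 and APOB stood at 13.21 and 11.01 on replicate 2 of day 4, and at 9.18 and 7.67 on replicate 1. At day 8 APOA2 was at 11.08 and 11.18 and APOB at 9.53 and 9.42, above the day 4 replicate left out.

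The separate position of replicate 1 of day 4 and of day 6 was set against 3 explanations. Remaining undifferentiated cells are argued against, as the pluripotency genes of these arrays allow a median share of 0.550% of day 0 RNA at day 4, where the raised genes would need 31.6% (lower quartile 15.6%), and 0.562% against 27.4% at day 6. Loss of 5' signal in degraded RNA stays open, because the ACTB ratio separates these arrays and the GAPDH ratio, 2.22 on replicate 1 of day 4, does not, since it divides the arrays by day. Slower progress from day 0 in replicate 1 may also contribute. Its difference from replicate 2 correlated across genes at -0.27 (day 4) and -0.39 (day 6) with the change from day 0 to day 8, and 68.4% and 74.4% of 2614 genes with a 2-fold change lay nearer day 0, so only day 6 passed the bound set for r and the test does not decide.

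Arrays with the same number at day 4 and day 6 correlated more closely (0.976 for replicate 1 and 0.974 for replicate 2) than the 2 arrays of day 4 (0.953) or of day 6 (0.937). Exchanged labels of replicate 2 of day 4 and replicate 1 of day 6 could give this, and so could a shared culture or array run of each number. Both predict a lower value of 0.974 and correlated differences of replicates at day 4 and day 6 (r = 0.600). The difference of replicates at day 8, which an exchange leaves in place, correlated with those of day 6 (r = 0.407) and day 4 (r = 0.188). A shared number predicts this and an exchange does not, and the GAPDH ratio also groups the arrays by labelled day (2.22 and 2.15 against 3.73 and 3.41). An exchange forbids neither, since day 8 arrays that differ along the course from day 4 to day 6 give such a correlation. Replicate 1 of day 8 itself correlated at 0.979 and 0.977 with replicate 2 of day 6 and of day 4. With replicate 1 of day 6 and of day 4 it correlated at 0.954 and 0.956, which a shared number does not predict. The 2 accounts cannot be told apart here. The labelled groups were kept throughout, although the source name of 3 samples of day 6 and day 8 gives day 4. That conflict was not weighed here, and no biological explanation was tested for this pattern.

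That no gene passed between sorted days might reflect the spread of replicates. At the measured spread 77.6% of simulated 4-fold changes between day 4 and day 8 were recovered. This is short of the bound set for calling the spread too small to hide them. The simulation changed 200 genes at once, with the spread drawn independently per gene. Replicate differences in the data were shared across genes, so this share cannot decide the question. HBE1 was higher by 5.04 ± 1.21 (SE), with 7.68 and 8.03 at day 4 and 13.13 and 12.66 at day 8. For HBE1 the spread of the day 6 arrays (7.59 and 11.97), which the comparison does not use, widened the error. The same held for HBD, at 6.37 and 6.42 at day 4 and 8.38 and 8.17 at day 8. Its day 6 arrays lay at 6.12 and 7.54. CD34 lay at 11.29 and 11.43 at day 4 and 11.60 and 11.64 at day 8, against 10.08 and 12.09 at day 6. For genes other than HBE1, HBD and CD34 the question stays open. The 13 genes over 4-fold apart between day 4 and day 8 had a median SD of 0.86 against 0.20 for all genes. The groups did not overlap in any of the 13 or in 189 of 221 genes over 2-fold apart. Choosing genes by a large difference of means itself favours no overlap, so these counts do not bear on the question. Day 4 and day 8 did not overlap in 38.0% of all genes, where chance gives 33.3%. The share was 24.4% between day 4 and day 6 and 25.5% between day 6 and day 8. A biological near-constancy of the sorted cells was not tested.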
